A study of Homo sapiens with 3 samples.

How the data were processed

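Single-cell suspensions of 1-week tri-cultures, and of the 3 cell types grown separately, were profiled with the 10x Chromium 3' v3.1 chemistry, per the labels' protocols. The age of the separate cultures at collection is not given in the sources used here, nor are the dose and duration of the lipopolysaccharide treatment. Libraries were sequenced on an Illumina NovaSeq instrument with reads of 100 bases and processed with Cell Ranger 7.2.0 against a 10x human reference of build GRCh38, per the labels' protocols and the submitters' processing notes. The files used hold, for each of 3 libraries, the list of barcodes in the filtered matrix and the list of genes, 6 files in all. The file names describe the lists as filtered, which in Cell Ranger output means barcodes called as cells. The settings of that call are not given in the sources used here. Neither list carries a measurement, and no table of values per gene and cell was used here. A treatment field in the labels names lipopolysaccharide for every library, so conditions were taken from the titles, which the design text explains. Each library is named by its title, TC_control, TC_LPS or IC_control, and each is the only library of its condition. All comparisons below therefore describe these libraries, without p-values.

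Before the data were examined, 26 gene lists, the rule for naming genes, the barcode comparisons and their alternatives were fixed. The rule for gene names without expression values was to name members that lack a row and at most 6 per list that have one. Comparisons of expression per cell class and of cell type shares were planned only for files with values per gene and cell. Those 3 comparisons and their 11 alternatives were not run. Genes named in the search of 3' ends were chosen after their values were seen, and some genes are not reported here.

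Each barcode line held 16 bases and a constant suffix, which was removed. A barcode was counted as shared when its 16 bases were identical in 2 libraries. The size of a common pool was estimated as the sum over the 3 pairs of the product of the list lengths, divided by the sum of shared barcodes, which gave 3803696 barcodes (95% interval 3281468 to 4434685). The expected number for a pair was the product of its list lengths over that size, which assumes that every barcode of the pool is drawn equally often. Pairs of barcodes at a Hamming distance of 1 or 2 were counted within and between libraries and divided by the number of pairs. Intervals are exact Poisson intervals at the 95% level, and a count of 0 is given with the limit that 3 counts would set. The counting functions were tested on 3 simulated lists, 47975 barcodes in all, with a known pool, planted shared barcodes and planted near-identical barcodes, and passed 6 of 6 checks. The planted near-identical barcodes differed at 1 base, so counts of pairs 2 bases apart were not tested with planted pairs. The simulated pool held random sequences, which the real pool need not.

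Gene identifiers were matched without version to GENCODE release 44 on GRCh38, the reference at hand. The genome build is the one the labels name, but the annotation release may not be, and 235 of the 36601 identifiers were not found in it. For 12952 of the matched identifiers the symbol differed from that in release 44, so the fixed lists were matched by the symbols in the gene rows. To ask which listed genes a 3' library can separate, each window of 100 bases in the last 500 bases of the protein-coding transcripts of a gene was searched on the sense strand in the release 44 transcripts of all genes that have a row. The depth of the libraries could not be assessed from these lists, so no statement on detection is made. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.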

Results

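Droplet single-cell RNA sequencing was carried out on 3 libraries of human stem cell-derived retinal ganglion cells, astrocytes and microglia, made from the WTC11 induced pluripotent line and the H7 embryonic line. Retinal ganglion cells are the projection neurons of the retina, astrocytes are supporting glia, and microglia are the resident macrophages of neural tissue. The library TC_control held untreated cultures in which the 3 cell types were grown together. The library TC_LPS held such tri-cultures treated with lipopolysaccharide, a component of the bacterial outer membrane that activates innate immune cells. The library IC_control held the 3 cell types grown separately, untreated, and combined. Each condition had 1 library, so no comparison between conditions has a replicate error and none was tested. Expression levels, cell type shares and the response of any gene were not analysed here, because the files used hold the cell barcodes and the gene rows of each library but no value per gene and cell.

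The design implies a comparison of TC_LPS with TC_control, which asks how inflammation changes the co-cultured cells, and one of TC_control with IC_control, which asks how growth together changes them. The values reported here for both are the number of barcodes called as cells. TC_LPS held 26956 barcodes and TC_control 13264, a ratio of 2.03 and a difference of 13692 barcodes. TC_control held 1.71 times the 7755 barcodes of IC_control, a difference of 5509. These numbers depend on how many cells were loaded and recovered as well as on the cultures, and with 1 library per condition the ratios have no error estimate. The same loading concentration, 700 to 1200 cells per µl, is stated for all 3 libraries, but this range does not give the number loaded in each. Whether each called barcode held a cell was not checked. Counts of molecules per barcode, and thus the depth behind each cell, were not analysed here. The labels state a target of about 50000 read pairs per cell.

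**Figure D1:**
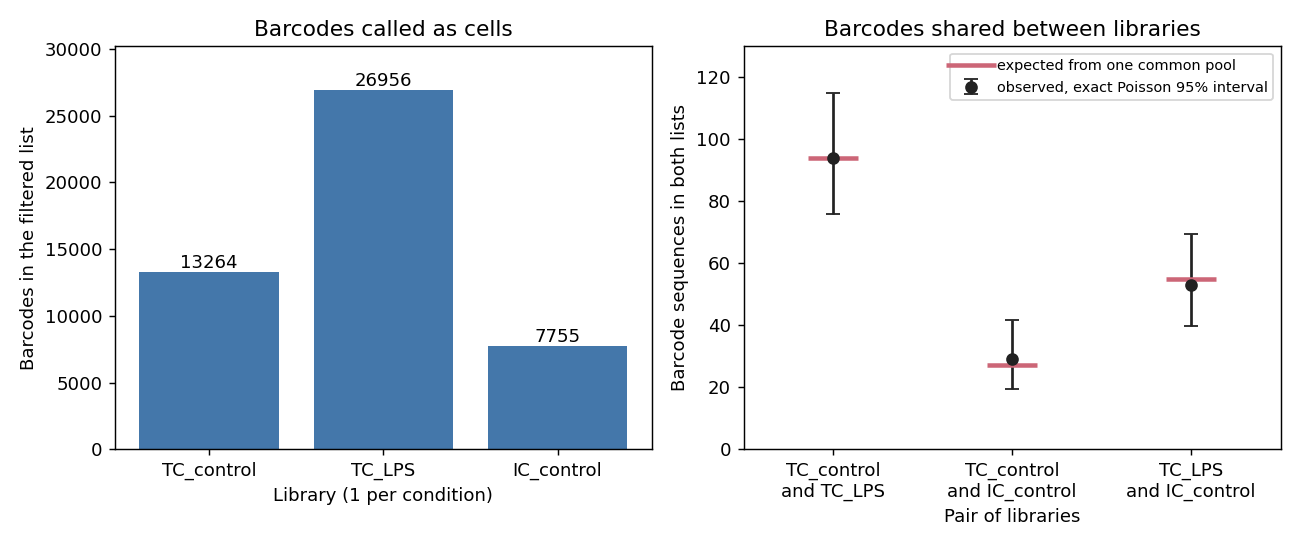
Left, bars give the number of barcodes in the filtered list of each library, from 7755 in IC_control to 26956 in TC_LPS. Right, points give the number of barcode sequences found in both libraries of each pair with exact Poisson 95% intervals, and horizontal marks give the number expected if all libraries drew from 1 common pool; each mark lies inside its interval.

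The same barcode sequence can occur in 2 libraries by chance, because each library draws its beads from a common pool of barcodes. TC_control and TC_LPS had 94 barcodes in common (exact Poisson 95% interval 76.0 to 115), TC_control and IC_control 29 (19.4 to 41.6), and TC_LPS and IC_control 53 (39.7 to 69.3). A single pool estimated from all 3 pairs predicted 94.0, 27.0 and 55.0 shared barcodes, so each observed count lay within its counting error of the prediction. The sum of the 3 predictions equals the sum of the observed counts by construction. Predictions made for each pair from the other 2 pairs alone were 94.0, 26.7 and 55.8. Barcodes also found in another library made up 0.92% of TC_control, 0.542% of TC_LPS and 1.04% of IC_control, and 1 barcode occurred in all 3.

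Pairs of barcodes that differed at 1 of their 16 bases were nearly absent within libraries. TC_LPS had 1 such pair, and TC_control and IC_control had 0, which allows up to 0.0341 and 0.0998 such pairs per 1000000 pairs of barcodes. Between libraries there were also 0 in each of the 3 pairs of libraries. The limits were 0.00839 per 1000000 for TC_control and TC_LPS, 0.0292 for TC_control and IC_control, and 0.0144 for TC_LPS and IC_control. The near absence is thus not particular to any library, and it was not read as evidence on droplets listed more than once. Pairs 2 bases apart occurred within libraries at 8.58 per 1000000 in TC_control (exact Poisson 95% interval 7.98 to 9.22), 8.56 in TC_LPS (8.26 to 8.87) and 9.51 in IC_control (8.44 to 10.7). Between libraries their rate was 8.87 to 9.09 per 1000000. These intervals and limits cover counting error only, and treat pairs as independent although 1 barcode enters many pairs.

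The gene rows were the same in all 3 libraries, with 36601 genes each, so no gene could be detected in 1 library and be missing from the annotation of another. Of the 36601 gene identifiers, 36366 (99.4%) were found in GENCODE release 44, where 19229 were annotated as protein-coding and 16421 as long non-coding RNA. The mitochondrial genome contributed 13 genes. Only 10 gene symbols stood on more than 1 row, and none of them was among the genes of the lists fixed for this study.

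All 230 distinct genes in 26 lists fixed before the data were examined had a row in every library. The lists covered 14 functions and 12 sets of cell type markers. A row shows only that a gene was in the annotation. It gives no evidence that the gene was expressed or that its reads could be told from those of similar genes. Among the genes named here, C1R shared 33.6%, NANOG 30.8%, POU5F1 8.19% and C3 1.88% of the 100-base windows at their 3' ends with another gene that has a row. The 6 genes chosen for sensing lipopolysaccharide were TLR4, the receptor, LY96, which encodes its co-receptor MD-2, CD14 and LBP, which deliver lipopolysaccharide to it, and the adaptors MYD88 and TICAM1. TLR4 (ENSG00000136869) lies on the plus strand of chromosome 9 from 117704175 to 117724735, LY96 (ENSG00000154589) on the plus strand of chromosome 8 from 73991392 to 74029079, and CD14 (ENSG00000170458) on the minus strand of chromosome 5 from 140631728 to 140633700. These positions span the whole gene in GENCODE release 44 on GRCh38, and all are annotated as protein-coding.

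The list of 22 NF-kB targets and cytokines included the inflammatory cytokines TNF, IL1A, IL1B and IL6 and the neutrophil-attracting chemokines CXCL8 and CXCL1. The 12 interferon response genes included ISG15, IFIT1, IFIT2, IFIT3, MX1 and MX2, which are induced by interferons. Of the 10 homeostatic microglia genes, P2RY12 and P2RY13 encode purinergic receptors and CX3CR1 the fractalkine receptor. The 12 genes of the disease-associated microglial state included TREM2, a lipid-sensing receptor, SPP1, LPL and GPNMB. The list of 16 complement genes included C1QA, C1QB and C1QC, the chains of C1q, with the proteases C1R and C1S. The 16 reactive astrocyte genes included the intermediate filament genes GFAP and VIM, the complement gene C3, and LCN2. The 10 genes of astrocyte maturation included the water channel gene AQP4 and the glutamate transporter genes SLC1A2 and SLC1A3.

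For neurons, the 15 genes of injury and apoptosis included the transcription factors ATF3, DDIT3 and JUN, and the 15 synaptic and maturation genes included SYN1, SYP, SNAP25 and DLG4. The 18 retinal ganglion cell markers included the transcription factors POU4F1, POU4F2, POU4F3 and ISL1, the RNA-binding protein gene RBPMS, and SNCG. The 16 astrocyte markers included S100B, SOX9 and NFIA, and the 17 microglia markers included AIF1, CSF1R, TYROBP and TREM2. Markers of cells that the cultures could also hold had rows as well, such as MKI67 and TOP2A for cycling cells, POU5F1 and NANOG for pluripotent cells, RAX for retinal progenitors, CRX and RCVRN for photoreceptors, and COL1A1 and DCN for mesenchymal cells.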

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

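Of the 19 alternatives planned before the data were examined, 11 concerned expression or cell classes and were not run, because no values per gene and cell were used here. The others gave 22 alternative values for 10 results. Of these values, 19 stayed within counting error of the value reported or, for counts, within 1.5 times of it. Many of the 19 had little room to differ, so they are weak evidence of stability. Almost no barcodes were 1 base apart, so those that added, merged or restricted such pairs had to stay nearly the same. The factor of 1.5 is also wide. The 3 that moved were the rates of near-identical barcodes within a library when pairs up to 2 bases apart were counted in place of pairs 1 base apart. They rose to 8.58 per 1000000 pairs in TC_control, 8.57 in TC_LPS and 9.51 in IC_control, since the wider definition adds all pairs 2 bases apart. Counting only barcodes found in no other library left 13142 in TC_control, 26810 in TC_LPS and 7674 in IC_control. Without replicates, the spread of barcode numbers between cultures of 1 condition is unknown, and no alternative here bears on it. No paired analysis was possible because each condition had 1 library.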

Other observations

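Both tests in the paragraph on barcode numbers and the search of 3' ends were chosen only after the results they concern, or the lists themselves, had been seen.

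Some genes chosen for inflammation share their 3' ends with other genes that have a row, which would make their counts uncertain in any 3' library. In 217 of 229 genes searched, no window of 100 bases in the last 500 bases occurred in another such gene. Each percentage below counts windows found in any other such gene. The partner named is the most frequent, and its own share is not reported here. C4A and C4B, which encode the isotypes of complement C4, shared 100% of their windows, most often with each other. Reads from their 3' ends therefore cannot be assigned to a single gene. ASNS, the asparagine synthetase induced by amino acid stress, shared 70.8%, most often with the overlapping locus AC079781.5. The complement protease gene C1R shared 33.6%, most often with C1RL, and the interferon-induced gene IFI6 29.0%, most often with LINC02574. Among markers of pluripotency, NANOG shared 30.8% of windows, most often with NANOGP8, and POU5F1 8.19%, most often with POU5F1B. HSPA1A shared 12.3%, most often with HSPA1B, and the chemokine gene CCL4 shared 5.28%, most often with CCL4L2. HSPA1B shared 0 of its own 401 windows, because windows came from the last 500 bases but were searched in whole transcripts. The windows of HSPA1A found in HSPA1B thus lie outside the last 500 bases of its coding transcripts. The 0 does not mean that HSPA1B holds no sequence shared with HSPA1A. Only windows identical over all 100 bases were counted, so genes with nearly identical 3' ends can pass as separate. TUBB3 and C3 shared 2.43% and 1.88% of their windows. SOD2 was not searched, since its identifier has no coding transcript in the release used. Windows weight every annotated coding transcript alike, whether or not these cells use it.

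TC_LPS held 13692 more barcodes than TC_control, and 2 technical sources were tested. Droplets listed under several near-identical barcodes would give TC_LPS a surplus of barcode pairs 2 bases apart. It had 3111 against 3251 predicted by the rate between libraries, a ratio of 0.957 (95% interval 0.924 to 0.991). That interval covers the count in TC_LPS but not the error of the prediction. It lies below 1, and the shortfall was not explained. Barcodes carried over from the other libraries would recur there, but only 146 did (95% interval 123 to 172). Summed over the pairs of libraries that include TC_LPS, 147 barcodes were shared against 149 predicted by a common pool. That pool was estimated from 176 shared barcodes that include these 147, so the closeness was largely set in advance. It cannot separate chance from carry-over, and the 146 are not an estimate of carry-over. Libraries outside this series were not covered. Both results argue against these 2 sources as the origin of the whole difference, since each would need to supply a number near it. The number of cells loaded, cell recovery, the threshold for calling cells, droplets split under unrelated barcodes, and a difference between the cultures all stay open and were not tested, and no biological explanation was tested.

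The estimated pool also gives the number of droplet pairs in a library that would carry the same barcode by chance and be merged into 1 entry. This calculation gave 95.5 pairs in TC_LPS (95% interval 81.9 to 111), 23.1 in TC_control (19.8 to 26.8) and 7.90 in IC_control (6.78 to 9.16). They correspond to 0.354%, 0.174% and 0.102% of the barcodes of each library. Such merged entries come on top of droplets that held more than 1 cell, whose number was not analysed here.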
